A study of Gossypium hirsutum with 6 samples.

How the data were processed

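RNA was sequenced from fibers of upland cotton (Gossypium hirsutum, strain 63) taken 5 days and 15 days after the day of flowering, named 5DPA and 15DPA (days post-anthesis). The labels give 3 libraries per stage and call them biological replicates. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, poly(A) RNA was selected with oligo-dT beads, fragmented, and sequenced as paired ends on an Illumina HiSeq instrument. No sequencing date, lane or library batch is given in the sources used here, so no batch could be set against the groups.

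The authors' table gives, per the file headers, a read count and an FPKM value for each gene in each library. The deposited counts are whole numbers that were not normalized. The deposited FPKM values equal the count divided by the gene model's length in kilobases and by the library's total in M counts, which was checked for each gene. The submitters' processing notes name HISAT and StringTie without versions. The genome build, the annotation, the counting settings and the use of strand are not given in the sources used here. Coordinates are printed as the file gives them, without a named build, and exon or UTR positions were not used here. The table held 73622 genes, of which 35834 lay on the 13 A chromosomes, 36291 on the 13 D chromosomes and 1497 on unplaced contigs. A further 2 lines of the table were empty and were left out. The library totals ran from 15.61 to 16.94 M counts. At these totals 1 read on a gene of 1 kilobase was worth 0.059 to 0.064 FPKM, and a gene with no read could have had up to 3 reads, a limit that covers counting error alone.

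Upland cotton carries 2 closely related subgenomes, A and D, and many gene families have near-identical copies. Reads that fit several copies may have been split or placed on 1 copy by the authors' counting, so values of single members of a family, and of the A and D copies of a gene, are uncertain. Overlapping genes and genes on opposite strands carry the same uncertainty.

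Genes with a mean FPKM of at least 1 over the 6 libraries were tested, which kept 40054 genes and 99.34% of the counts. The test was written before the data were examined as limma on log2(FPKM + 1), with edgeR's quasi-likelihood test to replace it if the table held counts. It did, so edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM scaling) in R 4.3.3 gave every reported fold change, SE and adjusted p, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 2-fold threshold, a log2 change of at least 1, was applied to edgeR's fold change. Every fold change is 15DPA over 5DPA. The common biological coefficient of variation was 28%. The script was tested on simulated counts for this comparison with 40054 genes, of which 200 were changed. It recovered 0% of genes changed 1.5-fold, 8% of those changed 2-fold, 60% of those changed 4-fold and 88% of those changed 8-fold, and called 4 of 39854 unchanged genes. In the real data 9357 genes were called, so the adjusted threshold was less strict there, and these shares do not give the sensitivity of the real comparison.

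Before the data were examined, 26 gene lists were fixed: 20 of wall, cytoskeleton, lipid, transport, hormone and phenolic genes, and 6 of background genes that stand for other tissues, dividing cells, handling and RNA selection. The rule written beforehand admitted a gene by symbol or by description. The table gives cotton genes no symbol of their own, only the gene name of the Swiss-Prot hit in another species, and these names were not used for the main lists, which departs from that rule as far as such a name counts as a symbol. A gene was placed in a list by its Swiss-Prot description, or by its NR description where it had none; 81.3% of the genes tested had a Swiss-Prot description. Description matching is imprecise: the pectin list also holds enzyme inhibitors, and a name ported from another plant does not show the same function in cotton. Lists with at least 3 tested members were tested with limma's camera (limma 3.58.1) on the edgeR fit with a preset inter-gene correlation of 0.01, and again with the correlation estimated for each list. GO terms with 10 to 500 tested members were tested the same way; 46.1% of the genes tested had a term.

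Named genes followed a rule fixed before the data were examined. It takes 1, 2 or 4 members of each list with the highest mean FPKM over the 6 libraries. It adds the 6 largest rises and the 6 largest falls on the log2(FPKM + 1) scale among genes with adjusted p under 0.05, stage ranges that did not overlap, a mean of at least 10 FPKM in the higher stage, and a description. Group values are means ± SD over 3 libraries in FPKM. A comparison of single values between groups of 3 cannot go below an exact two-sided permutation p of 0.1, so sums over lists are given with their SD and without a test.

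Alternatives written before the data were examined were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-ratio scaling, quantile normalization, limma without trend, the replicate number as a block, each library left out in turn, an estimated correlation, and DESeq2 1.42.0. The pseudocount, trend and quantile settings belong to limma on log2(FPKM + 1). Scaling by library totals alone, lists matched by NR descriptions, and an estimated correlation for all GO terms were added after the data were seen. Limma on log2(FPKM + 1), the main test written beforehand, was then also kept as an alternative. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Checks of GC content need the genome the counts were made on and were not made here.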

Results

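Gene expression was measured by poly(A) RNA sequencing in cotton fibers at 5DPA and 15DPA, with 3 biological replicates per stage. Cotton fibers are single cells that grow out from the seed coat epidermis. They elongate for weeks before they thicken with nearly pure cellulose. The series title places the work in fiber length development and names the CesA genes, which encode the catalytic subunits of cellulose synthase. The comparison asks which genes differed between an early and a later day of elongation. The 15DPA libraries held 16.3 ± 0.66 M counts and the 5DPA libraries 16.2 ± 0.549 M counts (SD, n = 3 each). Between 50146 and 52303 genes had reads in a library. The 100 most abundant genes took 16.9% ± 2.35 of the counts at 15DPA and 11.6% ± 1.26 at 5DPA.

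The stages separated on the first principal component, which held 65.4% of the variance. The 15DPA libraries lay at 89.7, 31.1 and 100.4 for replicates 1, 2 and 3, and the 5DPA libraries at −67.2, −94.8 and −59.2. Replicate 2 of 15DPA therefore lay nearest to 5DPA. Replicate 3 of 15DPA stood apart in another way. It held 35 genes with at least 20 reads that had at most 1 read over the other 5 libraries together, against 0 to 5 such genes in each other library. It also had no read of 26 genes with at least 20 reads in each other library, against 0 to 2 such genes elsewhere.

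**Figure D1:**
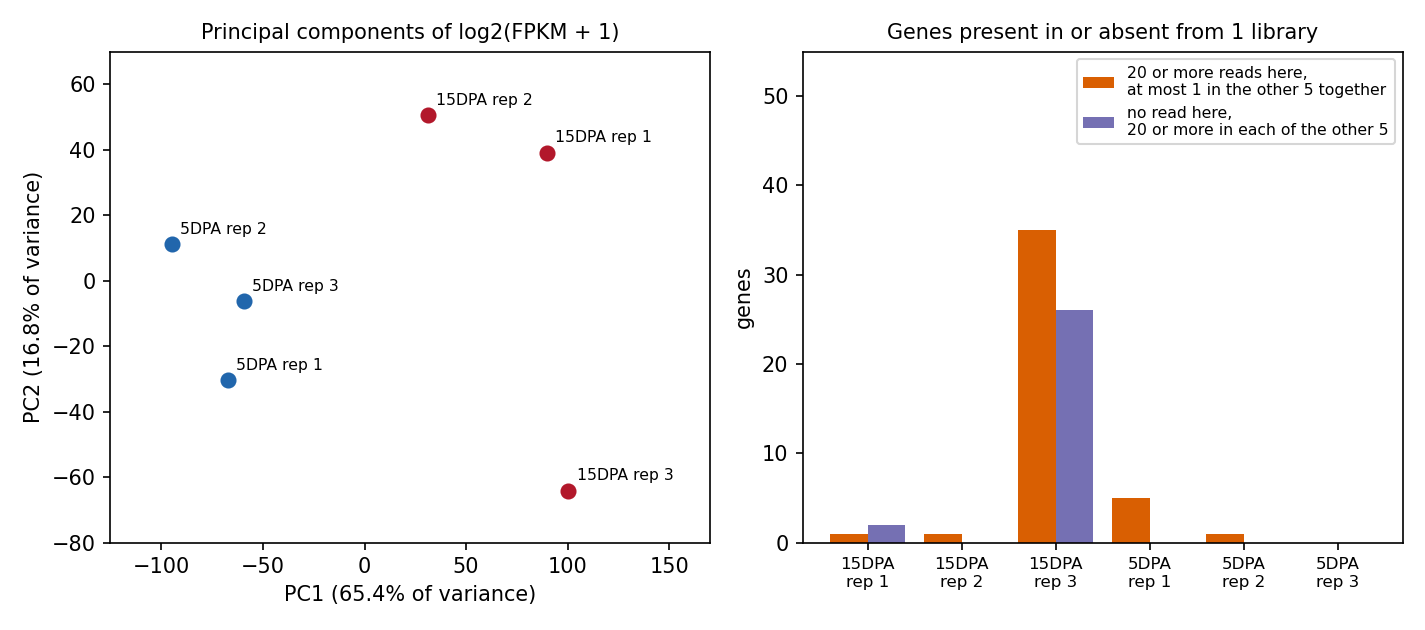
Left, principal components of log2(FPKM + 1) for the 6 libraries, with PC1 (65.4% of variance) against PC2 (16.8%), 15DPA in red and 5DPA in blue. Right, for each library, the number of genes with at least 20 reads there and at most 1 read in the other 5 together (orange), and of genes with no read there and at least 20 in each of the other 5 (purple); 15DPA replicate 3 has 35 and 26.

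Between 5DPA and 15DPA, 10 of 20 primary wall cellulose synthase genes and 25 of 59 tubulin genes rose. So did 20 of 44 very-long-chain fatty acid elongation genes. In the other direction, 260 of 690 ribosomal protein genes fell. In the list of 150 histone, mitotic cyclin and DNA replication genes, 68.7% were called lower, with a median log2 change of −1.87. Of 69 genes used in mitosis, matched separately by description, 10 were called lower, and their median was −0.86. Of 40054 genes tested, 9357 differed, with 5206 higher and 4151 lower at 15DPA (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were seen for 5050 of them, 2451 higher and 2599 lower. In FPKM, without TMM scaling, the ranges of the stages did not overlap for 50.2% of the genes tested, where chance gives 10%. That share also takes in any shift common to all genes, so 10% is not an exact reference. The direction of the calls followed the scaling between libraries. Under TMM 55.6% of calls were higher at 15DPA and the median log2 change was −0.04; with library totals alone 27.1% of 10609 calls were higher and the median was −0.33. Limma on log2(FPKM + 1), which has no scaling beyond library totals either, called 24.7% of 11839 genes higher. The FPKM values below have no TMM scaling, so the ratio of their means need not match the edgeR log2 change beside them. The count was 2319 without 15DPA replicate 1, 2338 without 5DPA replicate 2, 4234 without 5DPA replicate 3 and 4779 without 5DPA replicate 1. Without 15DPA replicate 2 or 3 it was 11434 or 9632.

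Primary wall CesA genes, whose products make the cellulose of growing walls, were abundant at both stages and 10 of the 20 tested rose at 15DPA. All 4 genes described as CesA1 were among them, with 3 of 7 described as CesA2, 3 of 7 described as CesA3 and neither of the 2 described as CesA6. The 20 genes summed to 459.8 ± 26.9 FPKM at 15DPA and 369.1 ± 21.6 FPKM at 5DPA (SD, n = 3 each). The secondary wall CesA genes, which make the cellulose of thickened walls, were near the lower limit of the genes tested at both stages. Only 3 of 12 annotated members reached a mean of 1 FPKM, and these summed to 4.6 ± 0.7 FPKM at 15DPA and 5.1 ± 0.3 FPKM at 5DPA.

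The most abundant CesA gene was Gh_A08G167200, described as CesA3, on A08 from 106293441 to 106300556. It held 75.6 ± 6.79 FPKM at 15DPA and 60.6 ± 4.22 FPKM at 5DPA, with a log2 change of 0.61 ± 0.16 (SE, edgeR adjusted p = 0.0302). Gh_D08G165700, also described as CesA3, on D08 from 53033009 to 53040226, rose by 0.65 ± 0.14 (SE, edgeR adjusted p = 0.0205). Gh_D05G009600, described as CesA1, on D05 from 842806 to 849400, went from 41.7 ± 1.18 to 60.7 ± 2.76 FPKM, and its log2 change was 0.84 ± 0.15 (SE, edgeR adjusted p = 0.0119). The CesA1 gene Gh_A05G007400, on A05 from 1025289 to 1031323, rose by 0.76 ± 0.15 (SE, edgeR adjusted p = 0.0154). Among the secondary wall members, Gh_D08G049700, described as CesA4, on D08 from 5190216 to 5195847, had 2.51 ± 0.173 FPKM at 15DPA and 2.11 ± 0.235 FPKM at 5DPA and did not pass the threshold (edgeR adjusted p = 0.0557). Gh_A08G054700, also CesA4, had 1.15 ± 0.207 and 1.53 ± 0.0972 FPKM, and Gh_D05G155000, described as CesA8, had 0.929 ± 0.394 and 1.46 ± 0.204 FPKM.

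By edgeR 0 of the 3 secondary wall members were called over all genes tested, 1 was called when adjusted over the list alone, and 1 had an unadjusted p under 0.05; DESeq2 called 0. Adjusted over the list alone, 10 primary wall members were called. By camera the primary wall list lay above other genes (adjusted p = 0.00123), a call lost at adjusted p = 0.366 with an estimated correlation. The primary wall count was 3 with library totals alone, 1 without 15DPA replicate 1, 1 without 5DPA replicate 2, 3 without 5DPA replicate 1 and 5 without 5DPA replicate 3. Limma on log2(FPKM + 1) called 5 primary wall genes higher and 1 lower. Of the 4 named primary wall genes none passed by edgeR without 15DPA replicate 1 or without 5DPA replicate 2, only Gh_D05G009600 passed without 5DPA replicate 1, and that gene and Gh_A05G007400 passed without 5DPA replicate 3. The highest adjusted p with a library left out was 0.118 for Gh_A08G167200, 0.0894 for Gh_D08G165700, 0.0571 for Gh_D05G009600 and 0.0693 for Gh_A05G007400. By limma, with library totals alone and under quantile normalization the log2 change of Gh_A08G167200 was 0.311, 0.315 and 0.411 and did not pass (adjusted p = 0.0897, 0.108 and 0.052), and that of Gh_D08G165700 was 0.349 with library totals alone (0.0586). The median of the secondary wall list was −0.12 and its mean 0.02, and the median turned to 0.19 under quantile normalization.

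**Figure D2:**
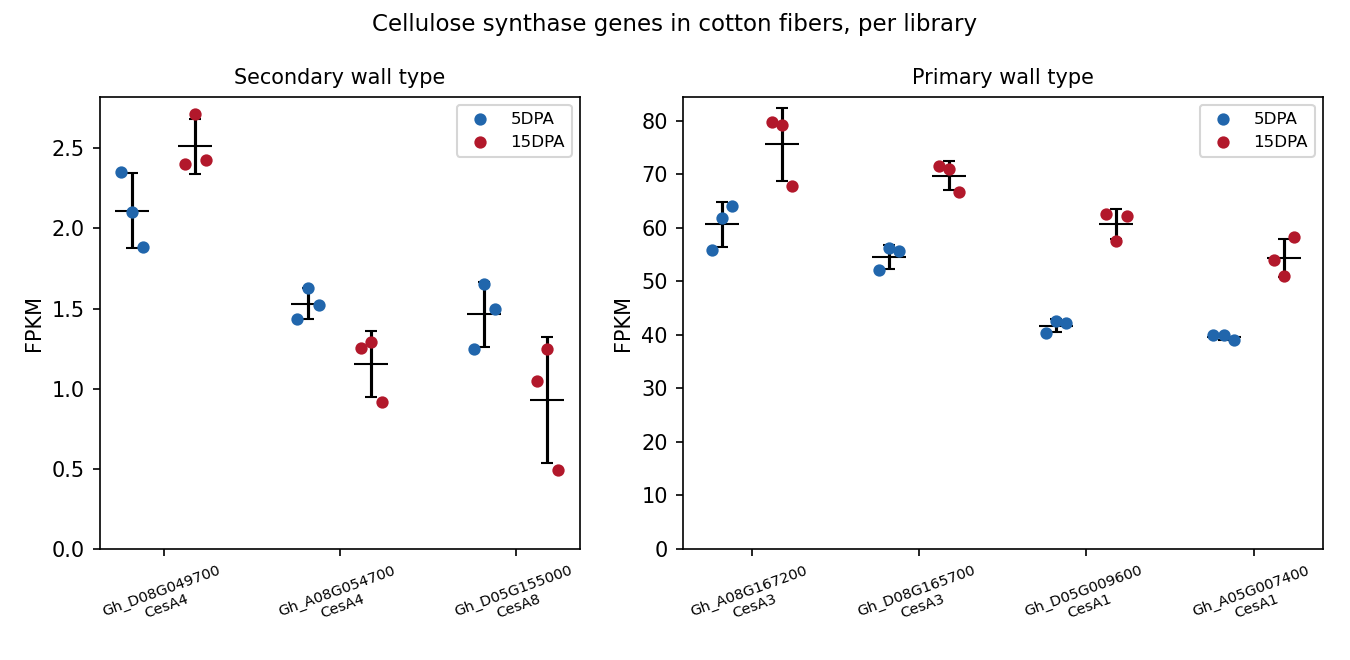
FPKM of the named cellulose synthase genes in each library, for the secondary wall type (left, 3 genes) and the primary wall type (right, 4 genes), with 5DPA in blue and 15DPA in red; points are libraries, dashes are means and bars are SD (n = 3). The 4 primary wall genes lie higher at 15DPA in each library, and the secondary wall genes lie below 3 FPKM at both stages.

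Of 38 genes in the list of secondary wall NAC and MYB regulators 4 were tested, and the 3 described as NAC domain-containing protein 43, a regulator of secondary wall formation in Arabidopsis, rose. Gh_D12G260500, on D12 from 59428872 to 59430213, went from 0.143 ± 0.117 to 4.48 ± 0.413 FPKM (log2 change 5.22 ± 0.48 SE, edgeR adjusted p = 0.00201). Gh_D03G096000, on D03 from 33524811 to 33526301, went from 0.326 ± 0.287 to 7.05 ± 2.62 FPKM (log2 change 4.73 ± 0.66 SE, edgeR adjusted p = 0.006). They had 5, 2 and 1 reads and 13, 1 and 7 reads at 5DPA, and with a library left out their log2 changes ran from 4.85 to 6.03 and from 4.19 to 5.55. The fourth regulator tested, described as MYB63, fell. Of 69 xylan and wall acetylation genes, 15 rose and 1 fell. The most abundant of these, the trichome birefringence-like 23 genes Gh_D03G092100 and Gh_A02G120400, rose by 1.17 ± 0.20 and 1.62 ± 0.18 (SE, edgeR adjusted p = 0.0106 and 0.00324). Of 28 fasciclin-like arabinogalactan protein genes, cell-surface proteins of fibers, 10 rose and 2 fell. Their sum was 6297 ± 1051 FPKM at 15DPA and 3666 ± 580 FPKM at 5DPA, led by Gh_A09G124800, on A09 from 66374775 to 66375506, with 2937 ± 616 and 1475 ± 357 FPKM (edgeR adjusted p = 0.0237).

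Sucrose synthase, which supplies UDP-glucose for cellulose, went the other way in sum: 9 genes summed to 794.8 ± 46.3 FPKM at 15DPA and 1575.1 ± 83.2 FPKM at 5DPA, with 3 lower and 1 higher by edgeR. Gh_D05G037800, on D05 from 3081072 to 3085623, fell from 727.6 ± 41.9 to 264.7 ± 38.2 FPKM (log2 change −1.16 ± 0.22 SE, edgeR adjusted p = 0.0125). Gh_A05G028400 had 340.9 ± 20.6 and 593 ± 62.9 FPKM at 15DPA and 5DPA and did not pass (edgeR adjusted p = 0.107). Of 25 cellulose assembly partner genes, such as COBRA-like and chitinase-like proteins, 10 rose. The chitinase-like 1 gene Gh_D10G004900 had 242.3 ± 18.4 and 200.8 ± 24.8 FPKM and did not pass (edgeR adjusted p = 0.0695). Of 36 cellulose synthase-like genes, which make other wall polysaccharides, 10 rose and 1 fell. The mannan synthase gene Gh_A09G110800 rose by 0.64 ± 0.18 (SE, edgeR adjusted p = 0.0399). The more abundant Gh_D09G104800, with the same description, had 75.1 ± 8.3 FPKM at 15DPA and 74.9 ± 13.3 FPKM at 5DPA. It did not pass (edgeR adjusted p = 0.316).

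Adjusted over the list alone, the higher and lower counts of these lists were 3 and 1 for the regulators, 16 and 1 for xylan and acetylation, 11 and 3 for fasciclin-like proteins, 1 and 4 for sucrose synthases, 13 and 1 for assembly partners, and 13 and 5 for cellulose synthase-like genes. Camera placed the regulators (adjusted p = 0.00143), xylan and acetylation (0.0129), assembly partners (0.00207) and cellulose synthase-like genes (0.0169) above other genes, each with adjusted p = 0.366 with an estimated correlation. The fasciclin-like (0.0771) and sucrose synthase (0.222) lists did not pass. Both NAC genes named had under 1 FPKM at 5DPA and met the filter through their 15DPA values. Which regulators were tested thus depended in part on the change itself, and the camera result for that list is not independent of the filter. With library totals alone the higher and lower counts were 4 and 5 for fasciclin-like genes, 8 and 6 for xylan and acetylation, and 8 and 6 for cellulose synthase-like genes, and by limma on log2(FPKM + 1) they were 4 and 6, 9 and 8, and 7 and 6. The xylan and acetylation median turned from 0.18 to −0.11 with library totals alone, and was 0.22 above the median of all genes. Camera did not call the regulators (adjusted p = 0.0525), assembly partners (0.0636) or cellulose synthase-like genes (0.244) without a filter, the cellulose synthase-like list under quantile normalization (0.0519), or xylan and acetylation at a mean FPKM of at least 5 (0.0572). It called the fasciclin-like list by limma (0.0227) and with library totals alone (0.0333), and sucrose synthases downward under quantile normalization (0.0231). Without replicates 1, 2 and 3 of 15DPA and then 1, 2 and 3 of 5DPA, each in turn, calls numbered 2, 13, 10, 4, 2 and 7 for assembly partners, 8, 19, 19, 10, 6 and 9 for xylan and acetylation, 3, 16, 14, 4, 4 and 7 for fasciclin-like genes, 7, 13, 13, 7, 7 and 8 for cellulose synthase-like genes, 1, 4, 6, 3, 2 and 2 for sucrose synthases and 2, 4, 4, 4, 3 and 4 for the regulators. Camera called the fasciclin-like list without 15DPA replicate 3 (adjusted p = 0.00375) and without 5DPA replicate 3 (0.0309). The NAC genes Gh_D12G260500 and Gh_D03G096000 and the gene Gh_A02G120400 passed without each library in turn. By edgeR Gh_D05G037800 did not pass without 15DPA replicate 1 (adjusted p = 0.0675), Gh_D03G092100 without 5DPA replicate 2 (0.0504), Gh_A09G124800 without 15DPA replicate 1 or 5DPA replicates 1 or 2 (up to 0.0937), and Gh_A09G110800 without any library other than 15DPA replicate 2 (up to 0.137). The log2 change of Gh_A09G110800 was 0.331 by limma, 0.34 with library totals alone and 0.422 under quantile normalization and passed in none of them (adjusted p = 0.0995, 0.102 and 0.0673), and Gh_A09G124800 did not pass under quantile normalization (0.0585).

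Genes of wall loosening changed in both directions, with a few very abundant ones higher at 15DPA. Expansins, which loosen growing walls, summed to 11870 ± 2306 FPKM at 15DPA and 5704 ± 1063 FPKM at 5DPA, yet of 42 genes tested 9 rose and 13 fell. The sum was carried by Gh_D10G123800, described as expansin-A8, on D10 from 19208807 to 19210097, with 5925 ± 1150 and 2647 ± 533 FPKM (log2 change 1.46 ± 0.31 SE, edgeR adjusted p = 0.0182), and by Gh_A10G149600, described as expansin-A2, with 5454 ± 1150 and 2645 ± 566 FPKM (edgeR adjusted p = 0.0242). Of 36 xyloglucan endotransglucosylase/hydrolase genes, 7 rose and 7 fell. Gh_D11G054000 of this family went from 404.7 ± 91.5 to 1100 ± 278 FPKM (edgeR adjusted p = 0.0122), while Gh_D11G064800 had 652.6 ± 52.8 and 673.6 ± 109 FPKM at 15DPA and 5DPA. Of 136 genes in the pectin list, 22 rose and 24 fell, and Gh_D03G117100, described as pectate lyase 18, rose by 1.69 ± 0.32 (SE, edgeR adjusted p = 0.0136). Gh_D05G037100, described as pectinesterase inhibitor 3, had 671.3 ± 49.1 and 893.3 ± 133 FPKM and did not pass.

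Adjusted over the list alone, 9 expansins rose and 15 fell, 8 xyloglucan genes rose and 8 fell, and 29 pectin genes rose and 30 fell. Camera called none of these 3 lists (adjusted p = 0.925, 0.925 and 0.832), and the xyloglucan list had a median of 0.01 with a test in the downward direction. Without replicates 1, 2 and 3 of 15DPA and then 1, 2 and 3 of 5DPA, each in turn, calls numbered 8, 22, 17, 10, 5 and 8 for expansins, 6, 15, 14, 12, 6 and 9 for xyloglucan genes and 17, 55, 57, 33, 19 and 25 for pectin genes. The expansin and xyloglucan medians, −0.01 and 0.01, changed sign with the scaling. With library totals alone the higher and lower counts were 7 and 15 for expansins, 7 and 10 for xyloglucan genes and 17 and 37 for pectin genes, and by limma on log2(FPKM + 1) they were 8 and 15, 7 and 11, and 18 and 40. By edgeR Gh_D10G123800 did not pass without 15DPA replicate 1 or 5DPA replicates 1 or 2 (adjusted p up to 0.0789), Gh_A10G149600 without any library other than 15DPA replicate 2 (up to 0.0973), and Gh_D11G054000 and Gh_D03G117100 without 15DPA replicate 1 or 5DPA replicate 2 (up to 0.0542 and 0.0569). Under quantile normalization Gh_A10G149600 did not pass (adjusted p = 0.107).

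More genes of the cytoskeleton, of very-long-chain fatty acid elongation and of water and proton transport rose than fell at 15DPA. Of 59 tubulin genes, 25 rose and 3 fell, and their sum was 15740 ± 2006 FPKM at 15DPA and 9430 ± 910 FPKM at 5DPA. The alpha-4 tubulin gene Gh_D05G216200 rose by 0.93 ± 0.25 (SE, edgeR adjusted p = 0.0366), and Gh_A03G209100, also described as alpha-4, had 1527 ± 202 and 1097 ± 124 FPKM (edgeR adjusted p = 0.0532); both turned negative, at −0.01 and −0.19, under quantile normalization. Of 85 actin and actin-binding genes, 28 rose and 6 fell, with Actin-58 (Gh_A05G354800) at 457.2 ± 70.2 and 301.2 ± 47.9 FPKM (edgeR adjusted p = 0.0356). Of 44 very-long-chain fatty acid elongation genes, 20 rose. These lipids are building blocks of membranes and cuticle. The 3-ketoacyl-CoA synthase 6 gene Gh_D01G206100, on D01 from 58634054 to 58635786, held 809.7 ± 96.9 and 451.5 ± 76.8 FPKM (edgeR adjusted p = 0.0176), and Gh_D02G188600 rose by 1.63 ± 0.27 (SE, edgeR adjusted p = 0.00935). Of 164 aquaporin and proton pump genes, 47 rose and 10 fell. The tonoplast aquaporin TIP1-1 gene Gh_A01G238700, on A01 from 114022648 to 114024219, went from 425.6 ± 70.3 to 1428 ± 208 FPKM (log2 change 2.05 ± 0.26 SE, edgeR adjusted p = 0.00458), and the PIP1-3 gene Gh_D08G204400 from 1010 ± 193 to 2394 ± 554 FPKM (edgeR adjusted p = 0.0138). Of 60 lipid transfer protein genes, 13 rose and 10 fell. The most abundant gene named here, Gh_A10G150000 of that family, on A10 from 84311440 to 84312162, held 9821 ± 987 FPKM at 15DPA and 5483 ± 1620 FPKM at 5DPA (edgeR adjusted p = 0.0357).

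Adjusted over the list alone, the higher and lower counts were 30 and 6 for tubulins, 37 and 11 for actins, 58 and 17 for aquaporins and pumps, and 14 and 10 for lipid transfer proteins, with 24 elongation genes higher. Camera placed tubulins (adjusted p = 3.96e-05), actins (0.000295), elongation enzymes (1.89e-09) and aquaporins and pumps (0.000406) above other genes, with adjusted p = 0.387, 0.41, 0.366 and 0.393 with an estimated correlation, and lipid transfer proteins did not pass (0.0771). With library totals alone the higher and lower counts were 17 and 4 for tubulins, 15 and 10 for actins, 28 and 21 for aquaporins and pumps, 17 and 1 for elongation and 11 and 10 for lipid transfer proteins, and by limma on log2(FPKM + 1) they were 17 and 9, 16 and 14, 32 and 23, 17 and 1, and 8 and 12. Camera did not call tubulins under quantile normalization (adjusted p = 0.0519, median 0.21), and called lipid transfer proteins by limma (0.00737) and with library totals alone (0.00762). Without replicates 1, 2 and 3 of 15DPA and then 1, 2 and 3 of 5DPA, each in turn, calls numbered 8, 31, 28, 12, 6 and 17 for tubulins, 8, 47, 26, 13, 10 and 15 for actins, 11, 25, 20, 12, 10 and 19 for elongation, 10, 76, 48, 30, 10 and 35 for aquaporins and pumps, and 12, 29, 20, 15, 12 and 15 for lipid transfer proteins. Gh_A01G238700 and Gh_D02G188600 passed without each library in turn. By edgeR Gh_D05G216200, Gh_A05G354800 and Gh_A10G150000 did not pass without any library other than 15DPA replicate 2 (adjusted p up to 0.142, 0.126 and 0.127), Gh_D01G206100 without 15DPA replicate 1 or 5DPA replicates 1 or 2 (up to 0.0753), and Gh_D08G204400 without 15DPA replicate 1 or 5DPA replicate 2 (up to 0.0625). Under quantile normalization Gh_D05G216200, Gh_A05G354800 and Gh_A10G150000 did not pass (adjusted p = 0.969, 0.146 and 0.447), nor did Gh_A10G150000 by limma (0.0577).

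Hormone genes changed in part. Of 27 genes of ethylene synthesis, 7 rose. The ACC oxidase gene Gh_A07G092800, whose product makes ethylene, on A07 from 13782489 to 13783832, went from 20.5 ± 0.991 to 85.3 ± 11.1 FPKM (log2 change 2.36 ± 0.18 SE, edgeR adjusted p = 0.00157). Another ACC oxidase gene, Gh_D05G175300, had 100.2 ± 164 FPKM at 5DPA and 23.6 ± 18.2 FPKM at 15DPA, and its log2 change turned from −1.81 to 2.38 without 5DPA replicate 1 (edgeR adjusted p = 0.41 and 0.134). Of 128 auxin-induced genes, 33 rose and 11 fell, with the SAUR71 gene Gh_D12G030800 at 267.5 ± 78.1 and 107.5 ± 22 FPKM (edgeR adjusted p = 0.0108) and the IAA9 gene Gh_D06G030500 at 109 ± 50.4 and 164.7 ± 13.7 FPKM (edgeR adjusted p = 0.425). Of 91 phenylpropanoid and lignin genes, 17 rose and 5 fell, among them Gh_D03G052400, described as cinnamyl alcohol dehydrogenase 9, at 551.7 ± 140 and 289.2 ± 13.9 FPKM (edgeR adjusted p = 0.0157). The cinnamate hydroxylase gene Gh_D10G202000 had 326.9 ± 110 and 322.1 ± 27.8 FPKM. Of 36 flavonoid genes, 3 rose and 2 fell, and without 15DPA replicate 3 as many as 14 rose and 1 fell. The chalcone isomerase-like genes Gh_A05G410100 and Gh_D04G012300 had 691.3 ± 264 and 600.4 ± 35.2 FPKM at 15DPA against 526.2 ± 49.1 and 525.5 ± 47.4 FPKM, and neither passed.

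Adjusted over the list alone, the higher and lower counts were 7 and 1 for ethylene, 34 and 16 for auxin, 17 and 5 for phenylpropanoid and 3 and 1 for flavonoid genes. Camera called the ethylene (adjusted p = 0.0475) and auxin (0.0398) lists, with adjusted p = 0.484 and 0.514 with an estimated correlation, and did not call the phenylpropanoid (0.138) or flavonoid (0.261) lists. The ethylene, auxin and phenylpropanoid medians turned from 0.01, 0.19 and 0.17 to −0.28, −0.10 and −0.11 with library totals alone, and the flavonoid median from 0.40 to −0.19 under quantile normalization; relative to the median of all genes the first 3 were 0.05, 0.24 and 0.23 with library totals alone. Without replicates 1, 2 and 3 of 15DPA and then 1, 2 and 3 of 5DPA, each in turn, calls numbered 5, 8, 7, 6, 5 and 5 for ethylene, 20, 46, 45, 23, 17 and 21 for auxin, 11, 24, 32, 15, 10 and 17 for phenylpropanoid and 3, 8, 15, 4, 3 and 3 for flavonoid genes. With library totals alone the higher and lower counts were 7 and 2 for ethylene, 24 and 16 for auxin, 14 and 9 for phenylpropanoid and 3 and 6 for flavonoid genes, and by limma on log2(FPKM + 1) they were 6 and 1, 24 and 20, 13 and 10, and 3 and 7. Camera did not call the ethylene list without a filter (adjusted p = 0.119), with median-ratio scaling (0.0564) or under quantile normalization (0.0519), nor the auxin list without a filter (0.115) or at a mean FPKM of at least 5 (0.199). It called the phenylpropanoid list by limma (0.0333), with library totals alone (0.025) and at a mean FPKM of at least 5 (0.0154). Camera did not call the ethylene list without 15DPA replicate 2 (adjusted p = 0.0934), 5DPA replicate 2 (0.107) or 5DPA replicate 3 (0.154), nor the auxin list without 15DPA replicate 2 (0.475, median −0.10) or 5DPA replicate 1 (0.0571), and called the phenylpropanoid and flavonoid lists without 15DPA replicate 3 (0.000611 and 0.000152). By edgeR Gh_A07G092800 and Gh_D12G030800 passed without each library in turn, and Gh_D03G052400 did not pass without 15DPA replicate 1 or 5DPA replicates 1 or 2 (adjusted p up to 0.0699).

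Of 150 histone, mitotic cyclin and DNA replication genes, 68.7% fell and 2 genes rose, with a median log2 change of −1.87, and their sum was 1919 ± 499 FPKM at 15DPA and 8017 ± 1808 FPKM at 5DPA. Matched separately by description, 25 of 50 DNA synthesis genes were called lower, with a median log2 change of −1.62. Of 69 genes used in mitosis 10 were called lower. Their median was −0.86 (quartiles −1.08 and −0.11), so most of this set lay lower as well. The histone H3.3 gene Gh_D03G042300, on D03 from 5026786 to 5027484, fell from 359.7 ± 70.8 to 111.3 ± 41.3 FPKM (log2 change −1.42 ± 0.24 SE, edgeR adjusted p = 0.01). In this list 15DPA replicate 2 summed to 2494 FPKM, against 1611 and 1652 FPKM in replicates 1 and 3. Of 690 cytosolic ribosomal protein genes, 260 fell, 4 rose and 426 were not called, and the sum went from 55613 ± 3803 to 36830 ± 865 FPKM. The most abundant of them, the S28 gene Gh_A01G145200, had 593.8 ± 73.7 FPKM at 15DPA and 696.2 ± 111 FPKM at 5DPA and did not pass (edgeR adjusted p = 0.802).

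Among lists that stand for other tissues or handling, 18 of 64 photosynthesis genes fell and 3 rose, from a low sum of 314.2 ± 47.3 FPKM at 5DPA to 215.3 ± 32.9 FPKM at 15DPA. The most abundant of them, Gh_A02G037100, a photosystem I subunit, went the other way, from 13.4 ± 4.04 to 25 ± 5.44 FPKM (edgeR adjusted p = 0.0309). Of 22 seed storage, oil body and late embryogenesis genes, 7 rose and 2 fell, with Gh_Contig00964G000900, described as Lea14, at 302.6 ± 21.1 and 220.3 ± 17.2 FPKM (edgeR adjusted p = 0.0262). Of 80 heat shock genes, 9 rose and 4 fell. Their sum was 6873 FPKM in 15DPA replicate 3, 2388 and 2267 FPKM in the other 15DPA libraries and 3504 to 3892 FPKM at 5DPA, and without 15DPA replicate 3 as many as 27 fell and 9 rose. The heat shock cognate 70 gene Gh_A11G374700 had 495.9 ± 146 and 405.1 ± 43.7 FPKM. A single organelle-encoded gene was tested, Gh_Contig00665G001200, with 6.18 ± 4.4 FPKM at 15DPA and 13.4 ± 5.18 FPKM at 5DPA (edgeR adjusted p = 0.3).

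Adjusted over the list alone, the higher and lower counts were 3 and 113 for dividing cells, 7 and 308 for ribosomal proteins, 4 and 19 for photosynthesis, 7 and 2 for seed genes and 9 and 2 for heat shock. Camera placed dividing cells (adjusted p = 1.06e-34), ribosomal proteins (9.08e-13) and photosynthesis (0.00054) below other genes and seed genes (0.0211) above, with adjusted p = 0.366, 0.366, 0.452 and 0.389 with an estimated correlation, and did not call heat shock (0.445). Without replicates 1, 2 and 3 of 15DPA and then 1, 2 and 3 of 5DPA, each in turn, calls numbered 49, 110, 104, 87, 60 and 84 for dividing cells, 61, 255, 213, 163, 68 and 96 for ribosomal proteins, 4, 23, 25, 5, 6 and 7 for photosynthesis, 2, 8, 9, 6, 4 and 5 for seed genes and 8, 22, 36, 5, 3 and 4 for heat shock. At a mean FPKM of at least 5 camera called neither photosynthesis (adjusted p = 0.639, median −0.05, 17 genes) nor seed genes (0.621, median −0.04, 14 genes), and without a filter it did not call seed genes (0.142). Heat shock counts were 9 higher and 10 lower with library totals alone and 8 and 12 by limma. Camera did not call the seed list without 5DPA replicate 3 (adjusted p = 0.0556), and called the heat shock list upward without 15DPA replicate 1 or 2 (0.0291 and 0.0123) and downward without 15DPA replicate 3 (0.00026, median −0.47). With library totals alone 465 ribosomal protein genes were called. By edgeR Gh_D03G042300 passed without each library in turn, Gh_A02G037100 and Gh_Contig00964G000900 did not pass without 15DPA replicate 1 or any 5DPA library (adjusted p up to 0.113 and 0.105), the latter gene did not pass under quantile normalization (0.0812), and the organelle gene Gh_Contig00665G001200 passed without 15DPA replicate 3 (0.0341).

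**Figure D3:**
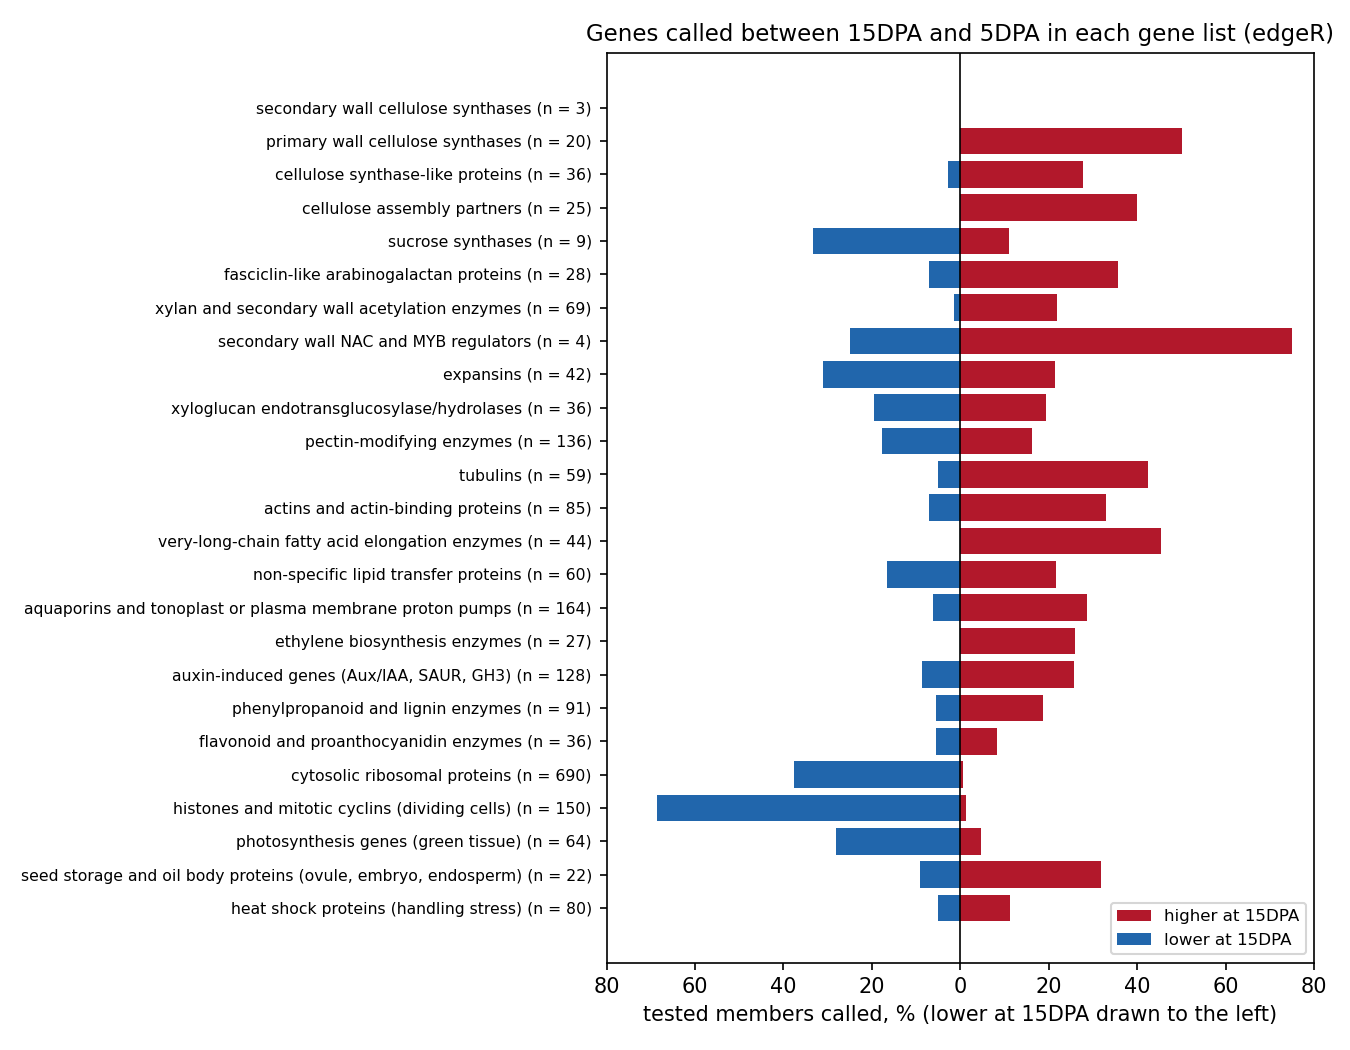
Percent of the tested members of each gene list called higher at 15DPA (red, to the right) or lower at 15DPA (blue, to the left) by edgeR, with the number tested beside each list. The dividing-cell list reaches farthest to the left, with 68.7% of 150 members lower, and the secondary wall cellulose synthases have no bar.

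By camera with the preset correlation, annotation terms of chromatin were lower and terms of membrane traffic higher at 15DPA. Of 549 GO terms tested by camera, 48 lay above and 40 below other genes. With an estimated correlation 0 of the 549 terms passed (smallest adjusted p = 0.838), and 13 had an unadjusted p under 0.05. Among the latter was nucleosome (camera unadjusted p = 0.0302). Vesicle-mediated transport (0.183), membrane coat (0.237) and intracellular protein transport (0.264) were not. The lower terms with the smallest p were nucleosome (64 of 95 genes fell, adjusted p = 1.37e-31), protein heterodimerization, which histones share (58 of 126 fell), large ribosomal subunit (20 of 48), DNA replication (28 of 80) and developmental process, whose fallen members were growth-regulating factors (13 of 25). The higher terms were acyltransferase activity (25 of 79 rose, adjusted p = 9.82e-06), vesicle-mediated transport (60 of 187), membrane coat (21 of 41), glycosyltransferase activity (46 of 117) and intracellular protein transport (69 of 250).

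Gh_A11G132100, a GPI-anchored lipid transfer protein gene on A11 from 13574959 to 13575950, went from 0.462 ± 0.422 to 114.1 ± 38.6 FPKM (log2 change 8.25 ± 0.61 SE, edgeR adjusted p = 0.00152). Gh_A05G404100, described as the alkane hydroxylase MAH1 of wax synthesis, on A05 from 106514605 to 106516137, went from 0.658 ± 0.205 to 111.6 ± 45.2 FPKM (edgeR adjusted p = 0.00146). Gh_D09G233000, an arabinogalactan protein 19-like gene on D09 from 50033456 to 50034412, went from 4.79 ± 0.308 to 487.1 ± 264 FPKM (edgeR adjusted p = 0.00164). Gh_D05G028500, described as Profilin-2, an actin-binding protein, went from 1.8 ± 0.721 to 130.1 ± 91.8 FPKM (edgeR adjusted p = 0.00289). Gh_D04G004800, described as vinorine synthase, went from 2.98 ± 1.42 to 127.3 ± 8.27 FPKM (edgeR adjusted p = 0.00152), and the uncharacterized gene Gh_D02G226700 from 0.437 ± 0.0757 to 70.6 ± 5.43 FPKM (edgeR adjusted p = 5.59e-05).

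The largest falls included a polyphenol oxidase gene, Gh_A06G204600, on A06 from 121351185 to 121353035, which went from 183.5 ± 31.1 to 5.72 ± 2.06 FPKM (log2 change −4.72 ± 0.33 SE, edgeR adjusted p = 0.00146). Gh_D01G024300, described as a fatty acid methyltransferase, went from 25.8 ± 10.5 to 0.494 ± 0.261 FPKM (edgeR adjusted p = 0.00164). The histone genes Gh_A03G052700 (H4) and Gh_A05G073100 (H2B) had log2 changes of −3.71 ± 0.55 and −3.58 ± 0.57 (SE, edgeR adjusted p = 0.00717 and 0.00865). Gh_A13G033200, described as RADIALIS-like 1, had 0, 1 and 1 reads at 15DPA and 34, 87 and 131 reads at 5DPA (edgeR adjusted p = 0.00458). Gh_A10G221800, described as a 21 kDa seed protein, had 6252 reads in 5DPA replicate 1 and 142 and 210 reads in the other 5DPA libraries, against 1 to 58 reads at 15DPA (log2 change −5.82 ± 1.74 SE, edgeR adjusted p = 0.0475). Its log2 change was −2.11 without 5DPA replicate 1 (edgeR adjusted p = 0.158), and its adjusted p lay between 0.0563 and 0.158 without each library in turn, so it passed in none of these, nor by limma (0.0607) or under quantile normalization (0.0873). The other largest rises and falls named here passed without each library in turn.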

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

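Library totals alone, NR descriptions, gene names of Swiss-Prot hits and an estimated correlation for all GO terms were chosen after the data were seen. Limma on log2(FPKM + 1) was the main test written beforehand. Only its use as an alternative to edgeR was added later. All genes called under TMM and under any alternative had the same direction in both. Of the 9357 these were 7032 with limma, 7030 with library totals alone and 2309 without 15DPA replicate 1. The fits share libraries, so agreement among genes called in both is a weak check and leaves out the other calls. The count of changed genes stayed within 1.5 times of 9357 under every alternative that kept the 6 libraries, and ran from 2319 to 11434 with a library left out, where the counts of 11434 without 15DPA replicate 2 and 9632 without 15DPA replicate 3 lay above 9357 although fewer samples are tested. The 2-fold count was 2705 at a mean FPKM of at least 5, where fewer genes are tested, and 1955 to 7002 with a library left out. For primary wall cellulose synthases the count of 10 became 6 with limma, 5 with a pseudocount of 0.1, 4 without trend, 3 with library totals alone and 1 to 10 with a library left out. For secondary wall cellulose synthases the count of 0 became 1 without a filter, where more genes are tested, and 1 with median-ratio scaling and 1 with quantile normalization, where Gh_D08G049700 passed. The 15 lists called by camera became 9 without a filter, 0 with an estimated correlation, 16 with NR descriptions, 16 with gene names of Swiss-Prot hits and 14 to 19 with a library left out. With gene names of Swiss-Prot hits the secondary wall cellulose synthase count became 4 and camera called that list (adjusted p = 0.0031), where the 9 genes gained are described as laccase and as xylosyltransferases and none as cellulose synthase. With these names camera also called the phenylpropanoid list (0.0155) and a list of 372 genes gathered as organelle-encoded (8.32e-09), which took in genes described as 40S, 60S and chloroplast ribosomal proteins, and did not call ethylene (0.0895) or seed genes (0.0681). Apart from fewer or more genes tested, the cause was not tested.

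Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at −0.217, 0.324 and 0.062. With the replicate block the counts were 8971 genes, 5064 at 2-fold, 0 secondary wall and 10 primary wall cellulose synthases and 14 lists, where camera did not call ethylene (adjusted p = 0.0586) or auxin (0.0516) and called lipid transfer proteins (0.0293).

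The 6 libraries were split into 3 and 3 in 10 ways, too few to give a share under 0.05. By edgeR the real split gave 9357 genes, 5050 at 2-fold and 10 primary wall genes. The other splits gave 0 of each, with 107 to 1502 genes at an unadjusted p under 0.05. Each other split holds both stages in each group, so the stage difference adds to the spread within groups. Few calls would follow from that alone, and the 0 does not measure chance. As large a result came from 1 of the 10 splits for each of these, and from all 10 for secondary wall genes, where the real and the highest other count were 0. Camera called 15 lists in the real split and 5 to 14 in the others, and 1 of 10 splits gave as many.

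Of the named genes that reversed, none was called under TMM apart from Gh_D05G216200. Quantile normalization gave 0.19 for Gh_A08G054700, 0.068 for Gh_D05G155000, −0.43 for Gh_D11G064800, −0.009 for Gh_D05G216200, −0.19 for Gh_A03G209100, −0.23 for Gh_D10G202000, −0.021 for Gh_A05G410100, −0.15 for Gh_D04G012300, −0.64 for Gh_A01G145200 and −0.059 for Gh_A11G374700. Limma gave −0.037 for Gh_D11G064800, −0.04 for Gh_D10G202000 and −0.22 for Gh_A01G145200, alike with a pseudocount of 0.1 and without trend. Library totals alone gave −0.049 for Gh_D11G064800 and −0.23 for Gh_A01G145200, which was −0.039 at a mean FPKM of at least 5. The block gave 1.20 for Gh_D05G175300. With a library left out, Gh_A08G054700 ran from −0.23 to 0.003, Gh_A01G145200 from −0.048 to 0.231 and Gh_D05G175300 from −2.374 to 2.379. Of 43 named genes called, 19 passed without each library in turn and 24 did not; 23 lost their call without 15DPA replicate 1, 23 without 5DPA replicate 2, 18 without 5DPA replicate 1, 13 without 5DPA replicate 3, 9 without 15DPA replicate 3 and 1 without 15DPA replicate 2. With the 6 libraries kept, 13 of the 43 lost their call in at least 1 setting: 12 under quantile normalization, 8 with limma without trend, 7 with limma, 7 with a pseudocount of 0.1, 5 with library totals alone and 1 with the block. The simulated recovery of 2-fold changes was 8%, with far fewer changed genes than were called here and so at a stricter adjusted threshold. It therefore does not give the sensitivity of the real comparison, which was not measured. For that reason genes that were not called are not shown to be equal.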

Other observations

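The tests of gene families outside the fixed lists were chosen after the data were seen, as were those of a mixed sample and of genotype for genes absent from 15DPA replicate 3, of depth for 15DPA replicate 2, of the mixture calculation in the other 15DPA libraries, and of ovule tissue.

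Outside the fixed lists, 982 families of at least 8 tested genes that share a description were tested by camera, of which 81 lay above and 52 below other genes; with an estimated correlation 0 passed, where the smallest adjusted p was 0.879. Growth-regulating factors fell in 17 of 29 genes, with a median log2 change of −1.49 and a sum of 120.5 ± 31.3 FPKM at 15DPA against 322.3 ± 28.9 FPKM at 5DPA (SD, n = 3 each). Their partners, the GRF1-interacting factors, fell in 6 of 11 genes (median −1.06). Zinc-finger homeodomain proteins fell in 15 of 25 genes (median −1.87), HMG-Y-related chromatin proteins in 11 of 13 (median −1.63) and the aspartyl proteases described as AED in 8 of 8 (median −2.74). Myosin-binding proteins, which link myosin motors to vesicles, rose in 15 of 22 genes (median 1.02, 276.7 ± 24.6 against 137.3 ± 5.8 FPKM). Exocyst EXO subunits rose in 17 of 37 genes with 1 lower (median 0.56), conserved oligomeric Golgi complex subunits in 14 of 22 (median 0.59), galacturonosyltransferases of pectin synthesis in 22 of 49 with 1 lower (median 0.56) and UDP-glucose 6-dehydrogenases in 5 of 10 (median 0.74). The sign of each of these medians was the same with library totals alone and under quantile normalization.

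The genes present in or absent from 15DPA replicate 3 alone, 35 and 26 with at least 20 reads, lay on 22 chromosomes and, for 2 of them, on contigs. The highest count among those present was 367 reads of Gh_D06G040700, described as an F-box/kelch-repeat protein, with 0 reads in each other library, and the highest mean of the other libraries among those absent was 167.4 reads, of Gh_A08G265800, described as a potassium transport protein; both were chosen after their values were seen. Lower depth is argued against, since Poisson sampling at its depth gives 6.74e-09 absent genes where 26 were seen. A mixture with other RNA would not by itself produce the absent part, since adding RNA leaves some fiber reads in place. Yet 26 genes with at least 20 reads in each other library had no read here, where any other library lacked at most 2 such genes. That count is the pattern itself and was known before the bound on a mixture was written, so it is no separate test. Plants of another genotype, with genes missing or too different to count, are a candidate explanation: among genes with 10 to 19 reads in the lowest other library, 44 were absent from this library and at most 5 from any other. These 44 genes extend the absence already seen to lower counts. The prediction written beforehand also asked for more genes present there alone at 10 to 19 reads. This was not met, with 17 there and 17 in 5DPA replicate 1. The tie also meets the bound written beforehand against genotype, so by the rule as written the joint prediction failed. An allowance for the counting spread, which the written bound does not hold, was applied to the tie. For the present part, genotype and other causes therefore cannot be told apart.

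Replicate 2 of 15DPA lay nearer to 5DPA than its partners, at 31.1 on the first component against 89.7 and 100.4. Low depth is argued against, since this library had the highest total, 16.94 M counts. A mixture with 5DPA RNA would give 1 share for all genes; genes far higher at 5DPA gave a share of 0.124 (95% bootstrap interval 0.107 to 0.14, 47 genes) and genes far higher at 15DPA gave 0.48 (0.431 to 0.519, 80 genes), a difference of 0.356. That difference is beyond the bound of 0.1 written beforehand, which would have argued against a mixture, but with replicate 2 left out of the calculation replicate 1 set against replicate 3 gave 0.352 (178 and 158 genes) and replicate 3 set against replicate 1 gave 0.164 (97 and 113 genes), where replicate 2 set against each of them gave 0.353 and 0.379. Since a library outside the pattern gave as large a difference, the bound was set aside after this was seen, and a mixture, a younger harvest and variation between plants cannot be told apart.

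The fall of histone and replication genes from 5DPA to 15DPA may reflect DNA replication without division in fibers, or dividing ovule cells in the 5DPA samples. DNA synthesis genes fell in 25 of 50 genes (median −1.62), and genes used in mitosis, matched by description with some unrelated genes such as calcyclin-binding proteins among them, fell in 10 of 69 with 2 higher, with a median of −0.86 (quartiles −1.08 and −0.11). Replication without division would leave the mitosis median above −0.5, and its exclusion needed −1 or lower with an upper quartile under −0.5, so the value lies between and decides neither. The prediction for carried-over ovule tissue was that mitosis genes and the green tissue and seed lists would all be lower at 15DPA. The mitosis median of −0.86 was lower. The green tissue list had a median of −0.84, but its most abundant gene Gh_A02G037100 rose from 13.4 to 25 FPKM. The seed list had a median of 0.83, with 7 of 22 genes higher and 2 lower, and so was not lower. No ovule sample was sequenced, so whether ovules at 5DPA express the seed genes is not known here. The seed list therefore cannot count against ovule tissue. At a mean FPKM of at least 5 the green and seed medians were −0.05 and −0.04. Because carried-over tissue and fiber age change together between the stages, these cannot be told apart, and a developmental change in the fibers stays open and untested.

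In 5DPA replicate 1, 97 genes lay at least 4-fold above each other library on the log2(FPKM + 1) scale, against 0 to 60 in the other libraries.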
